A study of Mus musculus with 13 samples.

How the data were processed

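RNA of sorted microglia from 13 mouse samples was measured by sequencing, 7 from animals exposed to repeated social defeat (RSD) and 6 from control animals (CON). Per the labels' protocols, brain cells were enriched on Percoll, stained for CD11b and CD45 and sorted, RNA was taken with the PicoPure kit, and libraries were made with the Ovation SoLo system with AnyDeplete removal of ribosomal RNA. Reads were aligned with STAR to mm10 and normalized with DESeq2, per the submitters' processing notes. The versions of both tools, the read counter, its annotation and its use of strand are not given in the sources used here.

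The deposited table gives a signal per gene and sample that is a read count divided by a sample's size factor. This was read from the values: within a sample, 100% of the values were whole multiples of 1 smallest step, within a tolerance of 0.01 reads, so the whole reads behind each value were recovered. Median-of-ratios size factors recomputed from those reads were 1.026 to 1.034 times the factors in the table. The table has 14518 gene entries, none with fewer than 9 reads over the 13 samples, and 1 symbol occurs on 2 of them. Of these symbols, 13790 were found in GENCODE M21 (GRCm38, the assembly also called mm10), 559 by a RefSeq synonym and 169 were not matched. A spreadsheet had turned 22 symbols into dates. No mitochondrially encoded gene was among the symbols used here, and ribosomal precursor RNA (Rn45s) was counted as a gene.

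The sequencing depth was 9.76 to 12.3 M recovered reads per sample. At this depth a gene of 100 reads has a counting error of about 10% in a library, and values of a few reads are uncertain by far more. Identifiers of single molecules were not used here, so any PCR copies left in the deposited values count as reads. No pair of libraries agreed within counting noise; the lowest chi-square per degree of freedom of any pair was 4.21, so all 13 were kept as separate samples. The labels do not say that each sample came from a separate animal, so p-values measure the spread between samples.

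The design, the gene lists, the rule for naming genes and a first set of alternatives were fixed before the data were examined. That design assumed raw counts and named edgeR's quasi-likelihood test as the first choice, with limma on log2 values if the table held normalized values. The table held normalized values, so the reported test is limma (3.58.1) on log2(value + 1) with a mean-variance trend and robust variance estimation, RSD against CON, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates those of low genes. Genes were kept by edgeR's filterByExpr on the recovered reads (minimum count 10, minimum total 15), which left 12496 genes. edgeR (4.0.16) with TMM factors and DESeq2 (1.42.0) were run on the recovered reads as alternatives, in R 4.3.3.

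29 gene lists were fixed from textbook knowledge. They cover microglial states, cytokines, interferon, glucocorticoid and stress hormone genes, immediate early and heat shock genes, cell cycle, antigen presentation, complement, lysosome, energy metabolism, cholesterol, TGF-beta, matrix, ribosomal proteins and markers of other cell types. The 25 lists with at least 5 kept members were tested with limma's camera at a preset correlation between genes of 0.01. The same lists were tested with a correlation estimated per list and with fry, a rotation test of whether a list's genes move one way on balance. List tests and marker scores used log2(value + 1), where the design had assumed log2 CPM. Marker scores, depth and detected genes were compared with exact two-sided permutation tests over all 1716 assignments of 13 samples to groups of 7 and 6.

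Genes were named by rule. If fewer than 12 genes passed in a direction, those of smallest p with a mean of at least 1 CPM (reads scaled to equal library sizes) were named until 6 stood in each direction. Up to 3 members of smallest p were named in each list, and P2ry12, Tmem119, Cx3cr1, Trem2, Apoe, Il1b, Tnf, Fkbp5, Tsc22d3 and Nr3c1 were named in any case. Some genes that the rule picks from the lists are not reported here, and list tests and counts include them.

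The limma step was tested on counts simulated for the same 12496 genes, with 7 against 6 samples and, over 10 simulations, 500 changed genes at each fold. It recovered 13.4% of genes changed 1.3-fold, 47.2% at 1.5-fold, 78.2% at 2-fold and 92.2% at 3-fold, and 4.7% of its calls were false. An interferon list shifted 1.3-fold was called in 10 of 10 simulations with 0 other lists. Genes were drawn independently with the spread seen in the data, so the simulated samples had no library that stood apart and no correlation between genes.

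Alternatives from that first set were other size factors, DESeq2, limma-voom with sample quality weights, edgeR with other factors, other filters, a fold threshold of 1.2, a surrogate variable (sva 3.50.0), removal of the 20 genes of largest share, the controls numbered 1, 4 and 5 or 17, 18 and 19 alone, and each sample left out in turn. Alternatives chosen after seeing the data were edgeR with TMM, limma with TMM factors, pseudocounts of 0.5 and 10, removal of CON 18 and RSD 8, a term for sample numbers 1 to 8 against 10 to 19, and each of those ranges of numbers alone. An estimated correlation for list tests in these subsets, and exact tests of marker scores permuted within ranges of sample number, were also chosen after seeing the data. The gene filter was run again in each subset of samples, so the tested members of a list can differ between settings.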

Results

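Microglia, the resident macrophages of the brain, were sorted as CD11b-positive cells with intermediate CD45 from 2-month-old C57BL/6 mice. The animals had gone through 6 cycles of repeated social defeat (RSD, n = 7), in which mice are repeatedly exposed to an aggressor, or had not (CON, n = 6). RNA was taken 24 days after the last cycle. The comparison of RSD with CON asks which microglial transcripts still differed at that time.

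Sequencing depth was 10.8 ± 0.83 M reads in RSD (SD, n = 7) and 11.3 ± 0.98 M in CON (SD, n = 6), a difference within the spread between samples (exact permutation p = 0.335). Between 14206 and 14428 genes had at least 1 read in a library, with means of 14313 ± 60.2 in RSD and 14315 ± 93.0 in CON (exact permutation p = 0.972). At least 5 reads were found for 13315 ± 123 genes in RSD and 13463 ± 147 in CON (exact permutation p = 0.0752). Ribosomal precursor RNA (Rn45s) took 3.77% to 7.80% of the reads and the nuclear long noncoding RNA Malat1 took 2.76% to 4.55%. Among the most abundant protein-coding transcripts were those of the microglial genes Csf1r (a mean of 76540 normalized reads), Cx3cr1 (44940) and P2ry12 (42650).

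Microglial identity genes overlapped between the groups. P2ry12, a purine receptor of surveying microglia, stood at 45140 ± 5614 normalized reads in RSD and 39740 ± 10450 in CON, a log2 difference of 0.24 ± 0.18 (SE). The library CON 18 held 18926.2 of it, and the other controls 39674.9 to 45971.6. Cx3cr1, the fractalkine receptor, stood at 45340 ± 4122 and 44490 ± 5917, and Tmem119 at 8100 ± 1555 and 8782 ± 1766. The cytokine genes Il1b (40.7 ± 4.01 and 44.9 ± 18.5) and Tnf (190 ± 43.1 and 253 ± 177) differed by less than the spread between samples, as did Trem2, a lipid-sensing receptor (3251 ± 748 and 3454 ± 416). For Tnf, CON 18 was at 604 normalized reads and the other controls were at 121.1 to 256. Apoe, a lipid carrier, was at 1324 ± 317 in RSD and 21660 ± 49630 in CON, where a single library, CON 18, held 123000.

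None of the 12496 genes tested passed an adjusted p of 0.05 in limma, where the smallest adjusted p was 0.821. At an unadjusted p under 0.05 there were 500 genes, 253 higher and 247 lower in RSD, against 625 that an even spread of p-values would give. That count was 1127 (9.0%) in limma-voom with sample quality weights and 1172 (9.2%) against CON 1, 4 and 5 alone. Within sample numbers 1 to 8, with 3 RSD and 3 CON libraries, it was 2776 (22.2%). These libraries also differed in the Spearman correlation of their deviation with transcript GC content, over genes of any length. It was -0.562, -0.052 and -0.725 in RSD 2, 7 and 8, and 0.189, 0.399 and 0.227 in CON 1, 4 and 5. The count of 2776 cannot tell social defeat from this GC contrast. List values given below for numbers 1 to 8 come from the same libraries and share this limit. edgeR also called 0 genes, with 601 under an unadjusted 0.05, and DESeq2 called 2 (Snord104 and Tex11), with 674. The median standard error of a log2 fold change was 0.13, and the median size of a log2 fold change was 0.11. Groups did not overlap at all for 8 genes, 4 higher and 4 lower in RSD, where chance gives 14.6 (0.117% of genes). These, named after their values were seen, were Snord104, Snord66, Bag4 and 1700001L05Rik on the higher side and Mavs, Dctd, Ctif and Nek6 on the lower.

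**Figure D1:**
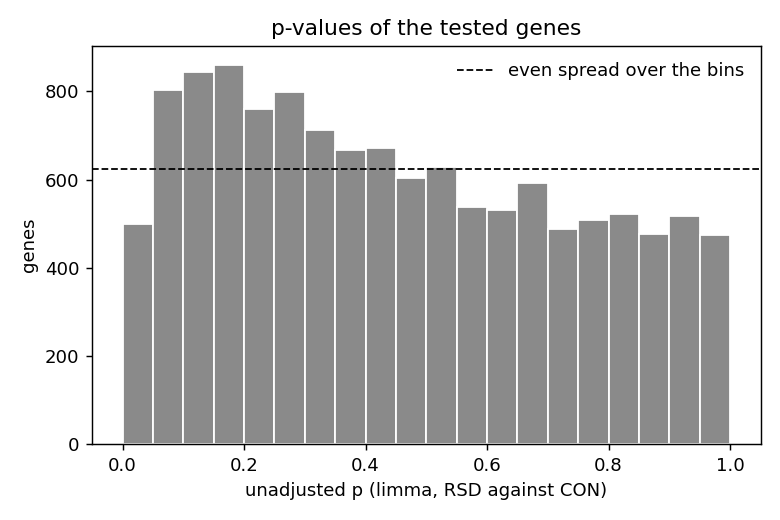
Histogram of unadjusted limma p-values (x axis, 20 bins from 0 to 1) for the 12496 tested genes (y axis, number of genes), RSD against CON; the dashed line is an even spread over the bins. The first bin holds 500 genes, below the dashed line at 625.

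**Figure D2:**
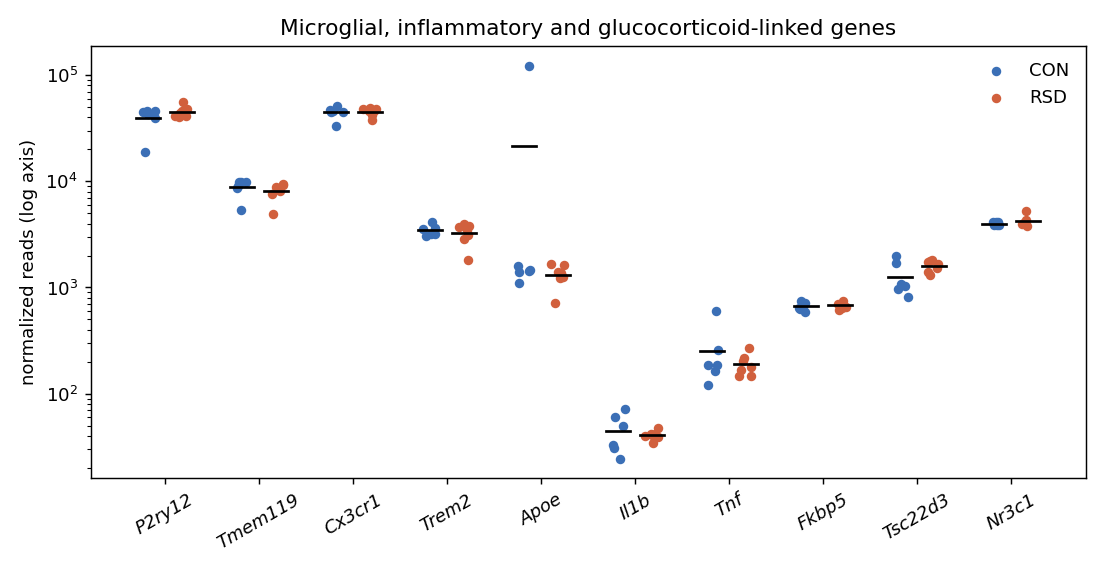
Normalized reads (y axis, log scale) of the 10 genes named in any case, with 1 point per library, CON in blue (n = 6), RSD in orange (n = 7) and black bars at the group means. The groups overlap for each gene, and the CON mean of Apoe (21660) lies far above 5 of the 6 CON points because of CON 18.

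Snord104, a small nucleolar RNA that guides methylation of ribosomal RNA, had the smallest p of the genes higher in RSD. It stood at 336 ± 129 normalized reads in RSD and 158 ± 41.5 in CON, a log2 difference of 1.05 ± 0.23, with every RSD library (233 to 568) above every CON library (105.7 to 197.2). Its adjusted p was 0.821 in limma and 0.804 in edgeR, and 0.0299 in DESeq2, where the log2 difference was 1.09. The gene lies at chromosome 11, 106500993 to 106501062 (mm10), with no overlapping gene in the annotation. Small nucleolar RNAs as a class took 0.272% ± 0.140 of reads in RSD and 0.194% ± 0.0934 in CON (exact permutation p = 0.266).

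Tex11, a meiosis gene of germ cells, had the smallest p of the genes lower in RSD, at few reads. It stood at 5.85 ± 5.44 normalized reads in RSD and 27.9 ± 13.1 in CON, a log2 difference of -2.33 ± 0.48, and the groups overlapped (RSD 1 to 16.7, CON 13.5 to 50.3). Its adjusted p was 0.821 in limma and 0.804 in edgeR, and 0.0299 in DESeq2, where the log2 difference was -2.26. Tex11 lies at chromosome X, 100838648 to 101059667, and holds a processed pseudogene and a pair of small nuclear RNA genes on its other strand.

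The other genes of smallest p had an adjusted p of 0.821 in limma as well. On the higher side were Nek1, a kinase linked to DNA repair and cilia (log2 0.27 ± 0.08; chromosome 8, 60993195 to 61131346), Tmem126b, an assembly factor of respiratory complex I (0.41 ± 0.12; chromosome 7, 90467438 to 90476001), and Mir568 (0.77 ± 0.22; chromosome 16, 43640655 to 43640737). Igsf10 (0.48 ± 0.14; chromosome 3, 59316735 to 59344394) and Dnajb13 (0.79 ± 0.23; chromosome 7, 100501716 to 100514960) completed that side. On the lower side were Rnf166, a ubiquitin ligase (-0.27 ± 0.07; chromosome 8, 122466147 to 122476064), Dctd, a deaminase of deoxycytidylate (-0.62 ± 0.18; chromosome 8, 48099092 to 48153233), and Mavs, the adaptor of cytoplasmic RNA sensing (-0.27 ± 0.08; chromosome 2, 131234063 to 131248025). Dynlt1f (-0.33 ± 0.10; chromosome 17, 6646602 to 6655900) and Zfp784 (-0.53 ± 0.16; chromosome 7, 5034439 to 5038446) completed it. Mavs stood at 544 ± 57.4 normalized reads in RSD and 653 ± 41.5 in CON, and Nek1 at 421 ± 32.0 and 348.9 ± 23.9.

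Several of these values are uncertain by their position. Mir568 lies inside Zbtb20 on the same strand. Igsf10 shares 1948 bases with Med12l, Dnajb13 shares 305 with Ucp2, and Zfp784 shares 4008 with Ccdc106, each on opposite strands. Nek1 overlaps predicted genes on both strands, and Rnf166 lies within Gm20388 on the opposite strand. Dynlt1f has near-identical copies that can share its reads.

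**Figure D3:**
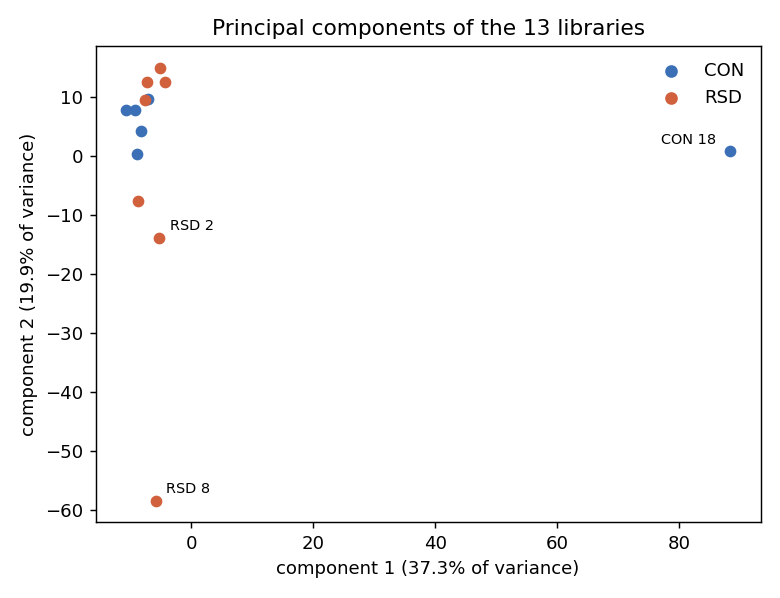
Principal components 1 (x axis, 37.3% of variance) and 2 (y axis, 19.9%) of log2(value + 1) over the tested genes, with 1 point per library, CON in blue and RSD in orange. CON 18 lies at 88.4 on component 1 and RSD 8 at -58.5 on component 2, away from the other libraries.

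A pair of libraries stood apart from the rest. CON 18 had a median Spearman correlation of 0.942 with the other libraries over genes, and RSD 8 had 0.968, where the others had 0.989 to 0.992. In CON 18 the macrophage genes Apoe (87.6-fold the median of the others), Axl (46.8-fold), Mrc1 (45.2-fold) and Lyz2 (17.9-fold) were high. The microglial transcription factor Sall1 stood there at 28.7% of the median of the others and P2ry12 at 42.7%. RSD 8 had 409 genes at less than 50% of the median of the others and 59 at more than 2-fold, and its Malat1 share was 4.55%. Without both libraries limma called 0 genes, with 612 under an unadjusted 0.05 and a smallest adjusted p of 0.10.

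Genes of protein folding stood highest among the fixed lists that are not cell type markers. The heat shock and unfolded protein response list had a mean log2 difference of 0.46 over 21 members, 17 of them positive, and limma's camera called it higher in RSD at an adjusted p of 4.26e-05. The call was lost with an estimated correlation (limma camera adjusted p = 0.67) and 0 members passed, over all genes tested and adjusted over the list alone. The mitochondrial chaperone genes Hspe1 (log2 0.62 ± 0.25) and Hspd1 (0.45 ± 0.19) and the cytosolic chaperone gene Hspa8 (0.48 ± 0.20) had the smallest p. The list's mean was 0.98 against CON 1, 4 and 5 alone and -0.07 against CON 17, 18 and 19 alone. Within sample numbers 1 to 8 it was 0.70 and within numbers 10 to 19 it was 0.14. In the latter range CON 18 had the lowest list mean (11.25), while CON 17 and 19 (11.60 and 11.69) lay within the RSD values (11.56 to 11.86).

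Ribosomal protein genes were the largest called group on the lower side. Of 77 members 71 were negative, with a mean log2 difference of -0.16, and limma's camera gave an adjusted p of 4.06e-14, or 0.67 with an estimated correlation. Rplp2 (-0.39 ± 0.14) and Rps15 (-0.24 ± 0.10) were among those of smallest p and none of the 77 passed. Without CON 18, which had the highest mean of this list (9.76), the mean was -0.10. CON 1, 4 and 5 were at 9.44 to 9.54, above the RSD libraries (9.21 to 9.40). CON 17 and 19, at 9.20 and 9.26, lay below or within the RSD range. The difference that was left without CON 18 thus rested on CON 1, 4 and 5. Nuclear-encoded oxidative phosphorylation genes had 50 of 70 members negative and a mean of -0.08 (limma camera adjusted p = 0.00644, and 0.67 with an estimated correlation). Among them were Ndufa3 (-0.43 ± 0.17) and Ndufc2 (-0.19 ± 0.08) of complex I, while Cycs, cytochrome c, was at 0.26 ± 0.11; the mean was 0.02 against CON 17, 18 and 19 alone. The call ended without CON 1 (mean -0.047, limma camera adjusted p = 0.157), without CON 5 (0.0505) and without RSD 13 (0.0634). Within sample numbers 1 to 8 the list was called at a mean of -0.174 (limma camera adjusted p = 0.00776, and 0.958 with an estimated correlation), and within numbers 10 to 19 the mean was 0.019 (limma camera adjusted p = 0.675). Glycolysis had 15 of 19 members negative and a mean of -0.09 (limma camera adjusted p = 0.0422, and 0.67 with an estimated correlation), with Gapdh at -0.24 ± 0.10, Gpi1 at -0.18 ± 0.11 and Hif1a at 0.22 ± 0.11. Its call ended when any of CON 1, 4, 5, 17 and 19 or RSD 2, 8 and 11 was left out, and without RSD 8 its mean was -0.03. Within sample numbers 1 to 8 it was called at a mean of -0.241 (limma camera adjusted p = 0.0147, and 0.958 with an estimated correlation), and within numbers 10 to 19 the mean was 0.034 (limma camera adjusted p = 0.375). In numbers 1 to 8 the list was lowest in RSD 8 and RSD 2 (8.55 and 8.81), the libraries with the strongest GC trends. RSD 7 (8.99) lay close to CON 1, 4 and 5 (9.01 to 9.05).

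Immune and macrophage-state lists were called lower in RSD with CON 18 in the controls. Antigen presentation had 17 of 20 members negative and a mean of -0.26 (limma camera adjusted p = 0.00644, and 0.67 with an estimated correlation), with H2-Aa at -0.98 ± 0.50, H2-DMa at -0.39 ± 0.19 and Cd86 at 3021 ± 499 normalized reads in RSD and 2641 ± 225 in CON. Disease-associated microglia genes had 17 of 22 negative and a mean of -0.21 (limma camera adjusted p = 0.0154, and 0.67 with an estimated correlation), with Ank at -0.27 ± 0.11, Tyrobp at -0.19 ± 0.09 and Cd68 at -0.20 ± 0.11. The type I interferon list had 21 of 27 negative and a mean of -0.18 (limma camera adjusted p = 0.0154, and 0.747 with an estimated correlation), with Stat2 at -0.21 ± 0.12, Rtp4 at -0.48 ± 0.27 and Xaf1 at -0.31 ± 0.18. Cell cycle genes had 22 of 25 negative and a mean of -0.17 (limma camera adjusted p = 0.0405, and 0.67 with an estimated correlation), with Cdc20 at -0.81 ± 0.37, Tyms at -0.26 ± 0.13 and Ccna2 at -0.33 ± 0.25. Lysosome genes had 25 of 31 negative and a mean of -0.05 (limma camera adjusted p = 0.0405, and 0.67 with an estimated correlation), with Psap at -0.17 ± 0.09, Mcoln1 at -0.21 ± 0.12 and Ctsl at 0.32 ± 0.15. Without CON 18 none of these 5 lists was called, and their means were -0.06 for antigen presentation, 0.02 for disease-associated genes, 0.08 for interferon, -0.02 for cell cycle and -0.02 for lysosome. Without RSD 8 the calls of antigen presentation (mean -0.162, limma camera adjusted p = 0.0738) and lysosome (mean -0.020, limma camera adjusted p = 0.258) also ended. The lysosome call further ended without CON 1, RSD 7 or RSD 11, and the interferon call without RSD 10, 11, 12 or 13. The cell cycle call ended without CON 5 (mean -0.083 over 26 members) or RSD 2, 7, 10, 12 or 13. Its mean was -0.353 over 27 members without CON 1 and -0.268 without CON 19. The interferon mean was -0.271 without CON 19. Interferon genes were called both ways by sample number. Within numbers 1 to 8 they were called higher in RSD, at a mean of 0.235 (limma camera adjusted p = 0.037, and 0.958 with an estimated correlation). Within numbers 10 to 19, which hold CON 18, they were called lower, at a mean of -0.537 (limma camera adjusted p = 5.45e-07, and 0.758 with an estimated correlation). The disease-associated mean was 0.021 within numbers 1 to 8 and -0.438 within numbers 10 to 19, with no call in either (limma camera adjusted p = 0.843 and 0.0784). Against CON 17, 18 and 19 alone the means were -0.46 for antigen presentation, -0.452 for disease-associated genes, -0.385 for interferon and -0.297 for cell cycle, each called by limma's camera, with an adjusted p = 0.645 for each with an estimated correlation.

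In all, limma's camera called 9 of 25 lists, 1 higher and 8 lower, while 0 were called with an estimated correlation and 0 with fry, where the smallest adjusted p was 0.663. No member of any list passed the limma threshold, over all genes or adjusted over the list alone.

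**Figure D4:**
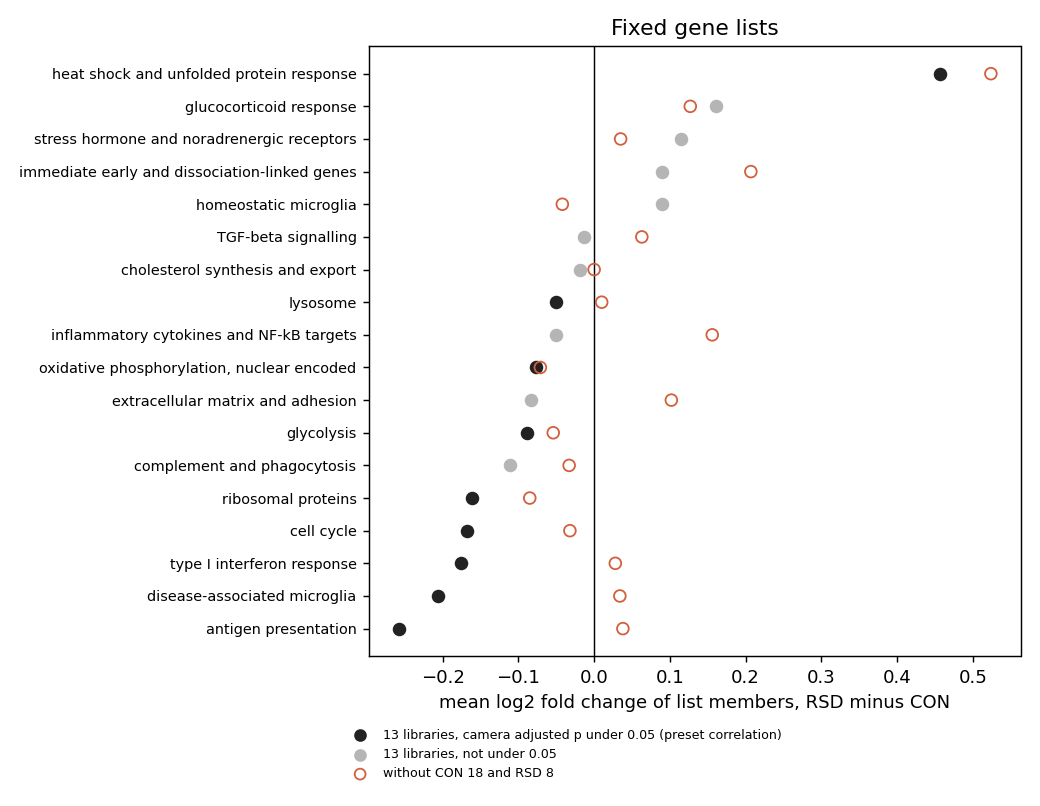
Mean log2 fold change of list members, RSD minus CON (x axis), for the 18 fixed lists that are not cell type markers (y axis); filled points use 13 libraries, black where limma's camera gave an adjusted p under 0.05 at the preset correlation, and open orange points leave out CON 18 and RSD 8. The heat shock list is at 0.46 and 0.52, while the disease-associated list is at -0.21 and 0.03.

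Stress hormone genes did not pass the test as lists. The glucocorticoid response list had 12 of 17 members positive and a mean of 0.16 (limma camera adjusted p = 0.295), with Tsc22d3, a glucocorticoid-induced leucine zipper gene, at 1605 ± 202 normalized reads in RSD and 1261 ± 462 in CON (log2 0.41 ± 0.18). The controls were split for Tsc22d3, with CON 1, 4 and 5 at 963.8 to 1080.1, CON 18 at 812.5, and CON 17 and 19 at 1970.9 and 1699.7. The RSD libraries ran from 1302.5 to 1817.2. All of them lay below CON 17, and RSD 2, 12 and 13 (1794.4, 1731.4 and 1817.2) lay above CON 19. Tgm2 stood at -0.26 ± 0.12 and Arrdc2 at -0.29 ± 0.16. Fkbp5, a co-chaperone gene induced by glucocorticoids, was at 677 ± 44.8 and 663 ± 62.2, and the receptor gene Nr3c1 at 4227 ± 486 and 3998 ± 136.5. Without CON 18 the mean of the glucocorticoid list was 0.084. The receptor list had 7 of 10 members positive and a mean of 0.12 (limma camera adjusted p = 0.285), which was 0.002 without CON 18. Adrb1 stood at a log2 difference of 0.15 ± 0.13 and the mineralocorticoid receptor gene Nr3c2 at 0.28 ± 0.27, with 111.6 normalized reads in CON 18 and 375.9 to 464.6 in the other controls.

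Of the other lists, homeostatic microglia had 14 of 20 members positive and a mean of 0.09 (limma camera adjusted p = 0.109), with Tgfbr1 at 0.15 ± 0.09 and Gpr34 at 0.21 ± 0.14. It was called higher without CON 1, 4, 5 or 19 or without RSD 8, with means from 0.107 to 0.126 (limma camera adjusted p = 0.716, 0.58, 0.607, 0.645 and 0.747 with an estimated correlation). Against CON 17, 18 and 19 alone the mean was 0.249 (limma camera adjusted p = 0.000226, and 0.645 with an estimated correlation), within numbers 10 to 19 it was 0.276 (limma camera adjusted p = 0.00117, and 0.758 with an estimated correlation), and without CON 18 it was -0.06. Without CON 18 and RSD 8 the mean was -0.04 and the list was called lower (limma camera adjusted p = 0.0336, and 0.482 with an estimated correlation). Inflammatory cytokine genes had a mean of -0.05 (limma camera adjusted p = 0.479), with Tnfaip3, an inhibitor of NF-kB, at 0.36 ± 0.19, Il1a at 0.20 ± 0.11 and Relb at -0.29 ± 0.17. Their mean ran from -0.124 without CON 5 to 0.12 without CON 18. Without CON 18 and RSD 8 their mean was 0.16 and the list was called higher (limma camera adjusted p = 0.00799, and 0.482 with an estimated correlation). With a term for the sample number as well the mean was 0.08 and the call ended (limma camera adjusted p = 0.115). Against CON 17, 18 and 19 alone the list was called lower, at a mean of -0.311 (limma camera adjusted p = 0.0011, and 0.645 with an estimated correlation). Immediate early genes, which also respond to cell dissociation, had 18 of 25 members positive and a mean of 0.09 (limma camera adjusted p = 0.295), with Btg2 at 0.22 ± 0.11, Fos at 0.29 ± 0.19 and Dusp6 at -0.21 ± 0.13. Without both libraries their mean was 0.21 and the list was called higher (limma camera adjusted p = 0.00021, and 0.482 with an estimated correlation). With a term for the sample number as well the mean was 0.075 and the call ended (limma camera adjusted p = 0.0777). Jun stood at 38030 ± 5038 normalized reads in CON and 38270 ± 6673 in RSD numbered 1 to 8, and at 51970 ± 5057 and 52550 ± 3454 in those numbered 10 to 19. The list was also called higher without CON 19 (mean 0.16; limma camera adjusted p = 0.652 with an estimated correlation), without RSD 8 (0.178; adjusted p = 0.696 with an estimated correlation) and against CON 1, 4 and 5 alone (0.279; adjusted p = 0.635 with an estimated correlation). Within numbers 10 to 19 it was called at a mean of 0.184 (limma camera adjusted p = 0.758 with an estimated correlation), and against CON 17, 18 and 19 alone its mean was -0.099. Some of the other removals lowered its mean, to 0.013 without CON 1, 0.017 without RSD 13, 0.033 without RSD 11 and 0.037 without RSD 12. Within numbers 1 to 8 the mean was -0.099.

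Complement and phagocytosis genes had 18 of 27 members negative and a mean of -0.11 (limma camera adjusted p = 0.295), with Fcer1g at -0.24 ± 0.08 and C1qc at -0.19 ± 0.10, and the mean was -0.045 without CON 18. Matrix and adhesion genes had a mean of -0.08 (limma camera adjusted p = 0.702), with Mmp2 at -0.26 ± 0.09, Itga5 at -0.23 ± 0.12 and Adamts1 at 0.53 ± 0.29. Without CON 4 that mean was -0.149, and without CON 18 it was 0.086. Without CON 18 and RSD 8 it was 0.10 and the list was called higher (limma camera adjusted p = 0.0393, and 0.482 with an estimated correlation). With a term for the sample number as well the call ended (mean 0.084, limma camera adjusted p = 0.0928). Cholesterol genes had a mean of -0.02 (limma camera adjusted p = 0.702), with Abcg1 at -0.15 ± 0.10 and Srebf2 at -0.19 ± 0.13. TGF-beta genes had a mean of -0.01 and a median of 0.02 (limma camera adjusted p = 0.941), with Smad6 at -0.56 ± 0.20 and Smad4 at 0.10 ± 0.06.

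Markers of other cells were tested as 7 lists and 0 of them differed between groups (exact permutation tests, adjusted p = 0.831 for each). Border-associated macrophage markers had a mean log2 level of 6.80 ± 0.27 in RSD and 7.06 ± 1.11 in CON, where CON 18 was at 9.32, with Ccl24 at 15.8 ± 7.67 and 7.74 ± 2.91 normalized reads and Folr2 and Stab1 at log2 differences of -0.49 ± 0.27 and -0.33 ± 0.21. Monocyte markers were at 4.52 ± 0.29 and 4.80 ± 0.67, with Ms4a4c at a log2 difference of -0.85 ± 0.66, Fn1 at -0.58 ± 0.50 and Nr4a1 at 0.39 ± 0.39. Ms4a4c was at 286.2 normalized reads in CON 18 and 6.3 to 15.1 in the other libraries. The monocyte markers Ccr2 and Plac8 were not high there, at 1.06-fold and 0.267-fold the median of the others. The mean log2 difference of the monocyte list was -0.278 with CON 18 and -0.051 without it. Neutrophil markers spread most, at 5.72 ± 2.14 and 5.03 ± 2.15, with S100a8 at 103 ± 121.5 and 48.4 ± 60.2 normalized reads, S100a9 at 149 ± 169 and 67.5 ± 84.1 and Camp at a log2 difference of 0.59 ± 0.62. The mean log2 difference of 0.684 became 0.217 without CON 19, 0.26 without CON 17, 0.30 without RSD 2 and 0.117 without CON 18 and RSD 8. It became 1.187 without CON 4, 1.16 without RSD 12 and 1.106 without CON 5 or RSD 13. Neutrophil markers followed the sample number. Against CON 17, 18 and 19 alone their mean log2 difference was 2.26 (limma camera adjusted p = 0.000226, and 0.645 with an estimated correlation), and against CON 1, 4 and 5 alone it was -0.95 (limma camera adjusted p = 0.204). With a term for the sample number limma's camera called the list higher in RSD (mean 0.946, adjusted p = 0.00594, and 0.71 with an estimated correlation). It did so also with both libraries left out (1.143, limma camera adjusted p = 0.00165, and 0.683 with an estimated correlation) and within numbers 1 to 8 (0.847, limma camera adjusted p = 0.0414, and 0.958 with an estimated correlation). Permuted within ranges of sample number, the difference was 0.95 (exact permutation p = 0.0971), and 0 of the 7 marker lists differed (smallest adjusted exact permutation p = 0.679). Neither the term nor this permutation can part social defeat from sample order within numbers 10 to 19, where RSD is numbered 10 to 13 and CON 17 to 19. The list mean fell within RSD there, from 5.40 and 5.29 in RSD 10 and 11 to 2.86 and 3.18 in RSD 12 and 13. It was 2.70 to 3.84 in CON 17, 18 and 19. Border-associated macrophage markers were called lower by limma's camera without RSD 8 (mean -0.456) and without RSD 12 (-0.567), with an adjusted p = 0.696 and an adjusted p = 0.599 with an estimated correlation. These means are those of the list without Ccl24, the only member that was higher in RSD over all libraries. Ccl24 no longer passed the filter there, so both calls also reflect a change of members. The list was also called lower against CON 17, 18 and 19 alone (mean -0.738, limma camera adjusted p = 0.0368, and 0.645 with an estimated correlation), and its mean was 0.183 without CON 18.

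Neuronal markers were at 5.54 ± 0.34 and 5.66 ± 0.47, with Calm2 at a log2 difference of 0.25 ± 0.15, Meg3 at -0.69 ± 0.88 and Syt1 at -0.30 ± 0.44. Their mean log2 difference of -0.116 became 0.051 without CON 5 and -0.22 without CON 19, and was -0.336 within numbers 1 to 8 and 0.155 within numbers 10 to 19. Astrocyte markers were at 6.47 ± 0.21 and 6.57 ± 0.34, with Clu at -1.81 ± 0.70, Fgfr3 at 0.80 ± 0.33 and Glul, which microglia also express, at 0.41 ± 0.22. The mean over this list was -0.10 while its median was 0.27, and the mean was 0.004 without CON 5 and -0.187 without CON 18. Oligodendrocyte markers were at 8.51 ± 0.17 and 8.62 ± 0.11, with Mbp at -0.23 ± 0.08 and Mag at -0.26 ± 0.17. Their mean log2 difference of -0.117 became -0.06 without RSD 8, and was -0.281 within numbers 1 to 8 and 0.021 within numbers 10 to 19. Endothelial and mural markers were at 6.05 ± 0.15 and 6.00 ± 0.30, with Kdr at 0.18 ± 0.14, Bsg at -0.09 ± 0.08 and Pecam1 at 0.37 ± 0.47; the mean log2 difference of this list was 0.04 and its median -0.01. Pecam1 was at 43.9 normalized reads in CON 18 and 375.9 to 461.2 in the other controls, and the list mean was -0.105 without CON 18. The lists of mitochondrially encoded genes, of T, NK and B cells, of erythroid cells and of ependymal and choroid plexus cells had fewer than 5 kept members and were not tested on the 13 libraries. In subsets where 6 ependymal and choroid plexus members were kept, limma's camera called that list lower in RSD against CON 1, 4 and 5 alone (mean -1.847, adjusted p = 0.000339, and 0.59 with an estimated correlation). The mean was -1.384 without CON 17, -1.268 without CON 19, -1.079 without CON 4 and -1.191 within numbers 1 to 8, each called by limma's camera, with an adjusted p = 0.517, 0.645, 0.563 and 0.958 with an estimated correlation. Against CON 17, 18 and 19 alone it was -0.181 (limma camera adjusted p = 0.658). Each subset with a call held CON 5, where the choroid plexus transcripts Ttr and Enpp2 were highest (1269 and 1646.8 normalized reads). RSD 7 (527.6 and 680.5) and RSD 10 (474.9 and 570.5) lay above CON 1 (349.6 and 426) and CON 4 (270.9 and 330.2), and the other RSD libraries lay below these controls.

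**Figure D5:**
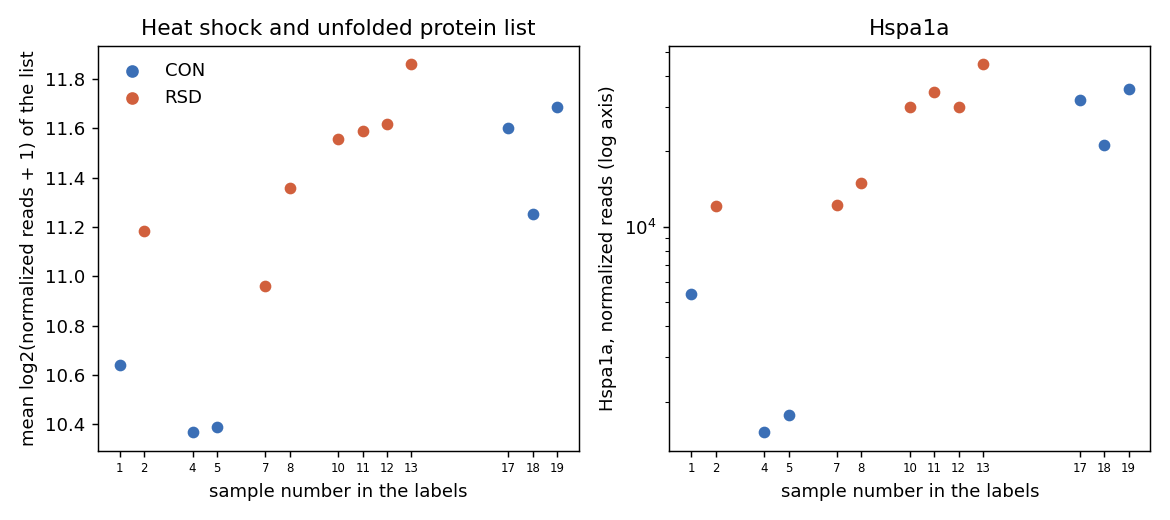
Left, mean log2(normalized reads + 1) of the heat shock and unfolded protein list per library (y axis) against the sample number in the labels (x axis); right, Hspa1a in normalized reads (log scale) on the same x axis; CON in blue (n = 6), RSD in orange (n = 7). Hspa1a is at 1506 to 5378 in CON 1, 4 and 5, at 12130 to 14880 in RSD 2, 7 and 8, and at 21170 to 44500 in the libraries numbered 10 to 19 of both groups.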

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

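The tests of CON 18, of the heat shock list and of RSD 8 in this part were chosen only after the results were seen, while the counts over other splits of the samples were chosen before. In each group the sample at either end was compared with its nearest neighbour (Dixon's test at 95%). Chance would mark about 1 in 20 groups, and 55 of 254 were marked, 31 through CON 18, 21 through RSD 8 and 3 through other libraries. The groups share libraries, and lists share genes with the named genes, so 1 library that stands apart marks many at once. The share marked is therefore no measure of an excess over chance. The counts include 1 gene value that is not listed. Values below are differences from the median of the group's other libraries, in log2 unless stated.

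CON 18 lay away from the other controls in its median Spearman correlation with the other libraries (-0.048) and in 11 list means. These were border-associated macrophage markers (2.76), interferon (1.57), disease-associated microglia (1.36), antigen presentation (1.17), inflammatory cytokines (1.00), matrix and adhesion (0.99), complement (0.39), glucocorticoid response (-0.47), stress hormone receptors (-0.69), endothelial markers (-0.70) and homeostatic microglia (-0.91). Its genes on the high side were Apoe (6.42), Ms4a4c (4.51), H2-Aa (2.69), Stab1 (1.21), H2-DMa (1.18), Ank (0.73), Mcoln1 (0.64) and Cd68 (0.46). Those on the low side were Pecam1 (-3.14), Nr3c2 (-1.76), P2ry12 (-1.25), Tmem119 (-0.88), Gpr34 (-0.87), Calm2 (-0.82), Igsf10 (-0.73), Cx3cr1 (-0.48), Bsg (-0.27) and Gapdh (-0.25).

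RSD 8 lay away from the other RSD libraries in its Malat1 share (1.425 percentage points), its median Spearman correlation (-0.022) and the means of antigen presentation (-0.69), endothelial markers (-0.37) and lysosome (-0.22). Its genes on the high side were Calm2 (0.58), Cd86 (0.52) and Tgfbr1 (0.47). Those on the low side were Mag (-1.16), Trem2 (-0.99), Apoe (-0.98), Relb (-0.96), Arrdc2 (-0.88), Tmem119 (-0.84), Stab1 (-0.77), Itga5 (-0.65), Cd68 (-0.57), Psap (-0.53), Tyrobp (-0.52), Gpi1 (-0.51) and Abcg1 (-0.47). The other 3 values were Tmem126b in CON 1 (0.31), Ctsl in RSD 7 (-0.13) and Kdr in CON 19 (-0.30).

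CON 18 had high macrophage genes and low microglial genes, and the excess of Apoe (123000 against a median of 1403) came with low Sall1 (28.7% of the others). Ordinary microglia diluted by cells that lack Sall1 would keep at least the Sall1 ratio for each microglial gene. Yet 28 of 8481 genes that are steady in the other libraries lay below 50% of the Sall1 ratio in CON 18 and 0 in any other library. This argues against dilution by such cells alone. Diluting cells that hold Sall1 themselves would make the ratio overstate the microglial share, and the test does not cover them. A first form of that test, on genes with a median of at least 500, gave 8 genes in CON 18 and 6 in the highest other library, was undecided and was replaced. An exchange of labels with an RSD library cannot be told apart, since 0 RSD libraries and 0 other CON libraries have Apoe within 2-fold of CON 18. Cells of another origin or state under this label may be the source and stay open too, with a median Spearman correlation of 0.942 that does not decide it, and no biological explanation was tested.

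The heat shock list was higher in RSD than in CON 1, 4 and 5, and it also followed the sample number, whose meaning the labels do not give. Within groups, libraries numbered 10 to 19 lay 0.75 above those numbered 1 to 8 (1.05 in CON, 0.49 in RSD; exact p = 0.00143, the smallest that 700 arrangements can give). Within ranges of sample number, RSD lay 0.40 above CON (0.70 in numbers 1 to 8 and 0.14 in numbers 10 to 19, exact permutation p = 0.0243). In numbers 10 to 19 CON 18 had the lowest list mean (11.25). CON 17 and 19 (11.60 and 11.69) lay within the values of RSD 10 to 13 (11.56 to 11.86), so the 0.14 rests on CON 18. Each RSD library in that range also has a lower number than each CON library, so an effect of order within it is not removed. The boundary between 8 and 10 was set after the data were seen, and both handling order and social defeat may contribute. Both stay open, and the difference between 0.70 and 0.14 was not tested.

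In RSD 8, GC-rich and short transcripts were low. Its deviation fell with transcript GC content over genes longer than 300 nt (Spearman rho -0.735, and -0.725 over genes of any length in a first form of the test), the strongest of the 13 libraries, with RSD 2 next at -0.572. Loss of GC-rich transcripts in library preparation is therefore a candidate explanation. A loss of short transcripts cannot be told apart from it here: genes of at most 300 nt lay -0.50 from longer genes of like GC, at the bound set for the test, with CON 5 at -0.42 and RSD 7 at -0.36. An earlier test by rho with length (0.179) was undecided, and no biological explanation was tested.

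Other splits of the 13 samples into groups of 7 and 6 were fitted with limma, 100 drawn at random with the real one included. For genes called (0 in limma, with 500 at an unadjusted p under 0.05, 0 in edgeR and 2 in DESeq2), each of the 100 splits gives as many by construction, the highest other giving 3, so this count says nothing on chance. Chance could not be excluded for the other 2 counts. For genes at an unadjusted p under 0.05 (500), 29 splits gave as many and the highest other gave 1747. That split, with 0 genes called, has CON 1, 4, 5 and 17 and RSD 7, 11 and 12 on one side and CON 18 and 19 and RSD 2, 8, 10 and 13 on the other. The latter side holds CON 18 and RSD 8, which stood apart, and RSD 2, whose GC trend was next to that of RSD 8. Whether this sets the sides apart was not tested. For lists called by limma's camera (9), 31 splits gave as many and the highest other gave 12, with a median of 7.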

How the results depend on the processing

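The settings with TMM on recovered reads, other pseudocounts, removal of CON 18 and RSD 8 and sample numbers, and the estimated correlation within these and other subsets, were chosen after seeing the data. No paired analysis was possible because the groups share no sample numbers. limma called 0 genes (500 at an unadjusted p under 0.05), DESeq2 2, edgeR 0, and limma with only CON 1, 4 and 5 as controls 5 (Dnaja1, Hsp90ab1, Hspa8, Fam46a and Dnajb1), 0 under each other setting. Genes at an unadjusted p under 0.05 were 1127 in limma-voom with quality weights, 152 against a fold of 1.2, 1172 with CON 1, 4 and 5, 324 without RSD 2, 765 with the sample-number term without CON 18 and RSD 8, and 2776 in numbers 1 to 8. The last count compares 3 RSD with 3 CON libraries, which also differed in their GC trend. List values for numbers 1 to 8 share this limit. For named genes 3182 of 3185 values kept their side of the threshold, with 65 sign changes in 22 genes, and 3 passed. For lists 512 of 624 values did, 51 of them with a change of sign, while 69 calls were lost, 20 were gained and 23 reversed. The 119 marker values kept their side, with 15 sign changes in 5 lists. Where a call or direction changed, the cause was not tested. Depth limits genes of few reads such as Tex11.

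Lists called, 9 in the report, were 4 with the first surrogate variable, 5 with CON 1, 4 and 5, 9 with CON 17, 18 and 19, 10 with the sample-number term, 7 without CON 18 and RSD 8, 5 with that term and without both, 7 in numbers 1 to 8, 4 in numbers 10 to 19, 0 with the correlation estimated per list and 0 with fry. With an estimated correlation 0 lists were called in any of these subsets of samples, with the sample-number term or leaving out each sample, the smallest adjusted p in limma being 0.0915 with CON 1, 4 and 5. Leaving out each sample gave 4 (without CON 18) to 11 (without CON 19), with disease-associated microglia from -0.268 (without CON 5) to 0.019 (without CON 18) and interferon from -0.271 (without CON 19) to 0.078 (without CON 18).

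Reversed list means were interferon 0.037 with the surrogate variable; disease-associated 0.039 and interferon 0.033 with CON 1, 4 and 5; heat shock -0.067 and oxidative phosphorylation 0.019 with CON 17, 18 and 19. Without CON 18 and RSD 8 they were homeostatic -0.042, disease-associated 0.034, inflammatory 0.156, interferon 0.028, antigen presentation 0.038, lysosome 0.010 and matrix 0.102. With the sample-number term as well they were homeostatic -0.042, disease-associated 0.034, interferon 0.085, antigen presentation 0.042 and lysosome 0.016. Numbers 1 to 8 gave disease-associated 0.021 and interferon 0.235, where interferon was called higher (limma camera adjusted p = 0.037, and 0.958 with an estimated correlation). Numbers 10 to 19 called it lower, at -0.537 (limma camera adjusted p = 5.45e-07, and 0.758 with an estimated correlation), and gave oxidative phosphorylation 0.019 and glycolysis 0.034.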

Other observations

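The clock tests in this part, and the genes named in it, were chosen only after the results were seen. Neutrophil transcripts followed the sample number in both groups. S100a8 stood at 96.5 ± 46.1 normalized reads in CON 1 to 5, 223 ± 80.5 in RSD 2 to 8, 13.9 ± 16.5 in RSD 10 to 13 and 0.376 ± 0.651 in CON 17 to 19. Ltf, lactoferrin, stood at 93.9 ± 70.6, 156 ± 28.3, 6.14 ± 8.19 and 1.07 ± 1.13 in the same order. The choroid plexus transcripts Ttr and Enpp2 were highest in CON 5 (1269 and 1646.8) and lowest in RSD 12 (10.2 and 9.2).

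Without CON 18 and RSD 8 the genes of smallest p included the clock-controlled transcription factor gene Hlf (152 ± 21.5 in RSD and 228 ± 28.2 in CON, limma adjusted p = 0.10) and the clock gene Per3 (440 ± 36.9 and 572 ± 67.2, limma adjusted p = 0.173). A hypothesis is that tissue was collected at different times of day, which would move evening-phase against morning-phase clock genes. The score tested was the mean log2 of evening-phase minus that of morning-phase genes. Since Hlf, Per3 and Tef had raised the question, 11 other clock genes were tested beside the whole list of 14. Without CON 18 and RSD 8 the score of the 11 genes was -0.19 in RSD against CON (exact permutation p = 0.00216, the smallest that 462 assignments can give), and that of the 14 was -0.28 with the same p. Among the 11, evening-phase genes had a mean log2 difference of -0.077 and morning-phase genes 0.109, with Nr1d1 at -0.385 ± 0.184, Per2 at -0.277 ± 0.184, Nfil3 at 0.283 ± 0.223 and Cry1 at 0.15 ± 0.162. Per1, an evening-phase gene, went the other way at 0.435 ± 0.264, and the morning-phase genes Arntl and Clock stood at 0.003 ± 0.089 and 0.002 ± 0.060. With all 13 libraries these differences were -0.12 (exact permutation p = 0.252) and -0.12 (exact permutation p = 0.563). A rotation test (limma's fry) came first and the exact permutation test was added after it. The rotation test gave p = 0.0271 for the 11 genes and 0.00285 for the 14 without both libraries, where the exact permutation test gave the values above. With a term for the sample number the rotation test gave 0.0669 and 0.00716, and with all 13 libraries it gave 0.226 and 0.387. The shift of the 11 genes rests on leaving out both libraries (exact permutation p = 0.00216 without them and 0.252 with all 13). These genes were scored in the same libraries that had raised the question, so they are not an independent test. Any difference in clock genes between RSD and CON would move the score, social defeat included, so it cannot decide on collection time. The hypothesis stays open, and collection times are not given in the sources used here.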
